A study of Rattus norvegicus with 6 samples.

How the data were processed

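Total RNA of rat oligodendrocyte precursors was extracted with ISOGEN and a silica column kit and hybridised with Cy5 to rat miRNA arrays, 1 sample per array, per the labels' protocols. The labels' protocol for labelling names an amplification kit made for messenger RNA, and how it was applied to miRNA is not given in the sources used here. Each scanner file holds the median intensity of 3200 spots and of the area around each spot, neither background-corrected nor normalized, and each array was scanned at 3 gains joined by straight lines, per the file headers. Of the spots 761 are rat miRNA probes, 3 of which name several miRNAs, 1664 are marked BLANK and 513 No Probe. A deposited value table holds a second set of intensity values, whose making the labels do not state. Set against the scanner values, each of its columns was a straight line of the spot intensity to within 0.522 units. The line starts at the trimmed mean of the array's blank spots and is scaled so that the median of each column is 25. Values were missing exactly where the spot did not exceed the blank mean by 2 SD in 99.9% of cells. The scale of those values is linear, no centring was found, and they were used only as an alternative.

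The local background could not serve as planned. Around each spot it followed the spot itself, with correlations of the log values of 0.939 to 0.982, so it was not independent of the spot. What ties them was not tested. This was found from the columns before any comparison was run, and the background was therefore taken from the blank spots, which the plan named only for files with no background column. The results given thus depart from the planned correction, and the version with the local background was run as an alternative. Spot intensities were corrected by normexp fitted on the BLANK spots (limma 3.58.1 in R 4.3.3, offset 50), put on the log2 scale and quantile-normalized over the 761 miRNA probes. The 1 miRNA spot with a scanner flag, miR-489-5p on the DIV0 array of replicate 1, was left out. A miRNA counted as detected where its intensity exceeded the blank mean by 2 SD, with the highest and lowest 5% of blanks left out. The 695 miRNAs detected on at least 3 of the 6 arrays were tested. Of the 761, 536 were detected on all arrays and 13 on none. Normalized levels of any 2 arrays correlated at 0.956 to 0.991 across miRNAs.

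Samples were grouped by their titles, which the culture condition in the labels follows. The 3 DIV3 arrays were compared with the 3 DIV0 arrays by lmFit and eBayes without trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The number of arrays limits the precision. Counts of detected miRNAs were compared by an exact permutation test, without and with pairs of equal replicate number. The titles give both conditions the replicate numbers 1 to 3. Arrays of equal number deviated together from their group means, with correlations of 0.37, 0.54 and 0.47 across miRNAs, against at most -0.02 with any array of another number. Deviations within a group cancel out, so positive values for equal numbers push the others down, and the contrast with -0.02 is partly arithmetic. From the positive values the numbers were taken to pair the samples. The main fit had no block, as planned, and the fit with the number as a block is given where it changes a call. Slides 1 and 2 held both arrays of replicates 1 and 2, and the arrays of replicate 3 lay on 2 separate slides.

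A total of 16 lists of miRNAs was fixed before the data were examined, from general knowledge of oligodendrocytes, miRNA families and other cell types. Lists were tested with camera at an inter-gene correlation of 0.01, and again with an estimated correlation and with fry, with adjustment over the lists. Camera compared the mean test statistic of a list with that of the other miRNAs, not their ranks. A list said to rank higher or lower did so by this mean. The rule for named miRNAs, also fixed beforehand, took those past the threshold with separated groups, up to 10 per direction, all tested members of the oligodendrocyte differentiation and the precursor and brake lists, and up to 4 members with the smallest p from each other list. It named 80 miRNAs. Tables of rat genes (assembly GRCr8) were used only to find which miRNA genes neighbour each other, with a match for 683 of the 695 tested miRNAs, and no coordinates are given because the build of the array is not given in the sources used here.

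The steps were tested on simulated data with 695 miRNAs, 60 of them changed, in 20 runs. For the comparison of DIV3 with DIV0, 56.8% of simulated log2 changes of 0.5 were found, 80.2% of those of 1 and 84.0% of those of 2, and 5.25% of the calls were false. Of the unchanged miRNAs 7.35% had an unadjusted limma p under 0.05. The simulated noise was independent between arrays and miRNAs, unlike the deviations that arrays of equal number shared. These rates therefore need not hold for the real arrays. The whole comparison was repeated under 27 alternatives: other background corrections and offsets, other normalizations, other filters, the deposited values, a trended prior, the replicate number or slide as a block, and each array left out in turn. Figures were drawn with matplotlib 3.10.9. GC content of the probes was not analysed here.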

Results

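MicroRNA levels were measured in cultured rat oligodendrocyte precursors, the cells that give rise to the myelin-forming oligodendrocytes of the central nervous system. The series compared 3 samples kept in the normal growth condition, titled DIV0, with 3 samples allowed to differentiate after a change of growth factors, titled DIV3. The numbers in these titles were read as days 0 and 3. Time in culture thus goes with the growth condition, and the 2 cannot be told apart. Each sample was hybridised to 1 single-colour Cy5 array with 761 rat miRNA probes among 3200 spots. The median miRNA spot lay 25.5, 37.7 and 5.87 intensity units above the blank spots on the DIV0 arrays of replicates 1, 2 and 3, and 27.9, 44.7 and 33.1 units above them on the DIV3 arrays. The DIV0 array of replicate 3 was thus much dimmer than the others, and its spike-in control spots averaged 6832 units against 27861 to 36833 on the other arrays. Nothing in the labels says that the samples came from separate cultures, so the p-values measure the spread between these 6 samples, which may be technical.

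Most probes gave a signal above the blank spots in both conditions. On the DIV0 arrays of replicates 1, 2 and 3, 696, 647 and 605 of the 761 miRNAs were detected, and on the DIV3 arrays 725, 662 and 633. The means were 649 ± 45.5 for DIV0 and 673 ± 47.0 for DIV3 (SD, n = 3 each), a difference of 24 with an exact permutation p of 0.6 without pairing (two-sided, where 3 against 3 samples cannot go below 0.1). Within the pairs of equal replicate number the DIV3 array had 29, 15 and 28 more detected miRNAs than the DIV0 array, higher in 3 of 3 pairs. The mean of these differences was 24 ± 7.81 (SD, n = 3 pairs, exact permutation p within pairs = 0.25, two-sided, the smallest that 3 pairs allow). With the threshold taken from the No Probe spots they were 64, 16 and -49. Without 1 pair the mean was 21.5 to 28.5, while leaving out 1 array, which breaks a pair, gave -1.83 without the DIV3 array of replicate 1 and 1.83 without the DIV0 array of replicate 3. No miRNA was detected on all 3 arrays of one condition and on none of the other. Detection against blank spots is a permissive criterion, since 32.6% to 45.2% of the spots marked as carrying no probe also passed it.

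The first question was which miRNAs differ between the differentiated and the normal condition. The largest rises among the miRNAs past the threshold belonged to miR-219, miR-338 and miR-138, which are known from oligodendrocyte biology as miRNAs that accumulate when precursors differentiate. The miR-219a-5p level was 10.5-fold higher in DIV3, a log2 fold change of 3.40 ± 0.54 (SE, n = 3 per group, limma adjusted p = 0.036). In the deposited values its mean went from 113 ± 139 to 1285 ± 431 intensity units (SD, n = 3). Its partner from the opposite arm of one precursor, miR-219a-2-3p, rose by a log2 fold change of 1.64 ± 0.20 (adjusted p = 0.023). The level of miR-138-5p was 4.92-fold higher, with a log2 fold change of 2.30 ± 0.26 (adjusted p = 0.020), and deposited means of 86 ± 56.5 and 612 ± 101. For miR-338-3p the fold was 4.67 and the log2 fold change 2.22 ± 0.23 (adjusted p = 0.018), with deposited means of 137 ± 72.9 and 889 ± 218.4. The other strand of its precursor, miR-338-5p, rose by 0.95 ± 0.10 on the log2 scale (adjusted p = 0.018). These fold changes are on the scale of log2 background-corrected intensity with 50 units added, which understates the change of dim probes.

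In all, 14 of the 695 miRNAs tested passed an adjusted p of 0.05, 8 higher and 6 lower in DIV3, and 102 had an unadjusted p under 0.05. The other 3 that rose came from precursors of miR-181, a family abundant in brain: miR-181b-1-3p (log2 fold change 0.71 ± 0.10, adjusted p = 0.032), miR-181a-1-3p (0.68 ± 0.09, adjusted p = 0.024) and miR-181b-5p (0.34 ± 0.06, adjusted p = 0.041). Of these only miR-181b-5p is on the list of the miR-181 family tested below. The spot of miR-181b-1-3p adjoins that of miR-219a-5p, and its change came to 3.70% of that of its neighbour. The 6 that fell changed by less than 2-fold. They were miR-211-3p (-0.88 ± 0.14), miR-21-5p, a miRNA abundant in proliferating cells (-0.78 ± 0.13), miR-328a-5p (-0.66 ± 0.10), miR-299a-3p (-0.54 ± 0.09), miR-335 (-0.52 ± 0.07) and miR-762 (-0.47 ± 0.08), with adjusted p-values of 0.032 to 0.037. In the deposited values the mean of miR-21-5p was 2835 ± 536 in DIV0 and 1723 ± 63.4 in DIV3. Only 4 of the 14 differed by 2-fold or more. The 3 DIV3 values of each of the 14 lay on one side of the 3 DIV0 values. All 14 therefore also went the same way in each of the 3 pairs of equal replicate number. As the 14 were picked by their p in these same arrays, neither is separate support. Such separation held for 131 of the 695 miRNAs, or 18.9%, where chance gives 10% if the 6 arrays are exchangeable. With deviations shared by arrays of equal number that share need not hold.

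**Figure D1:**
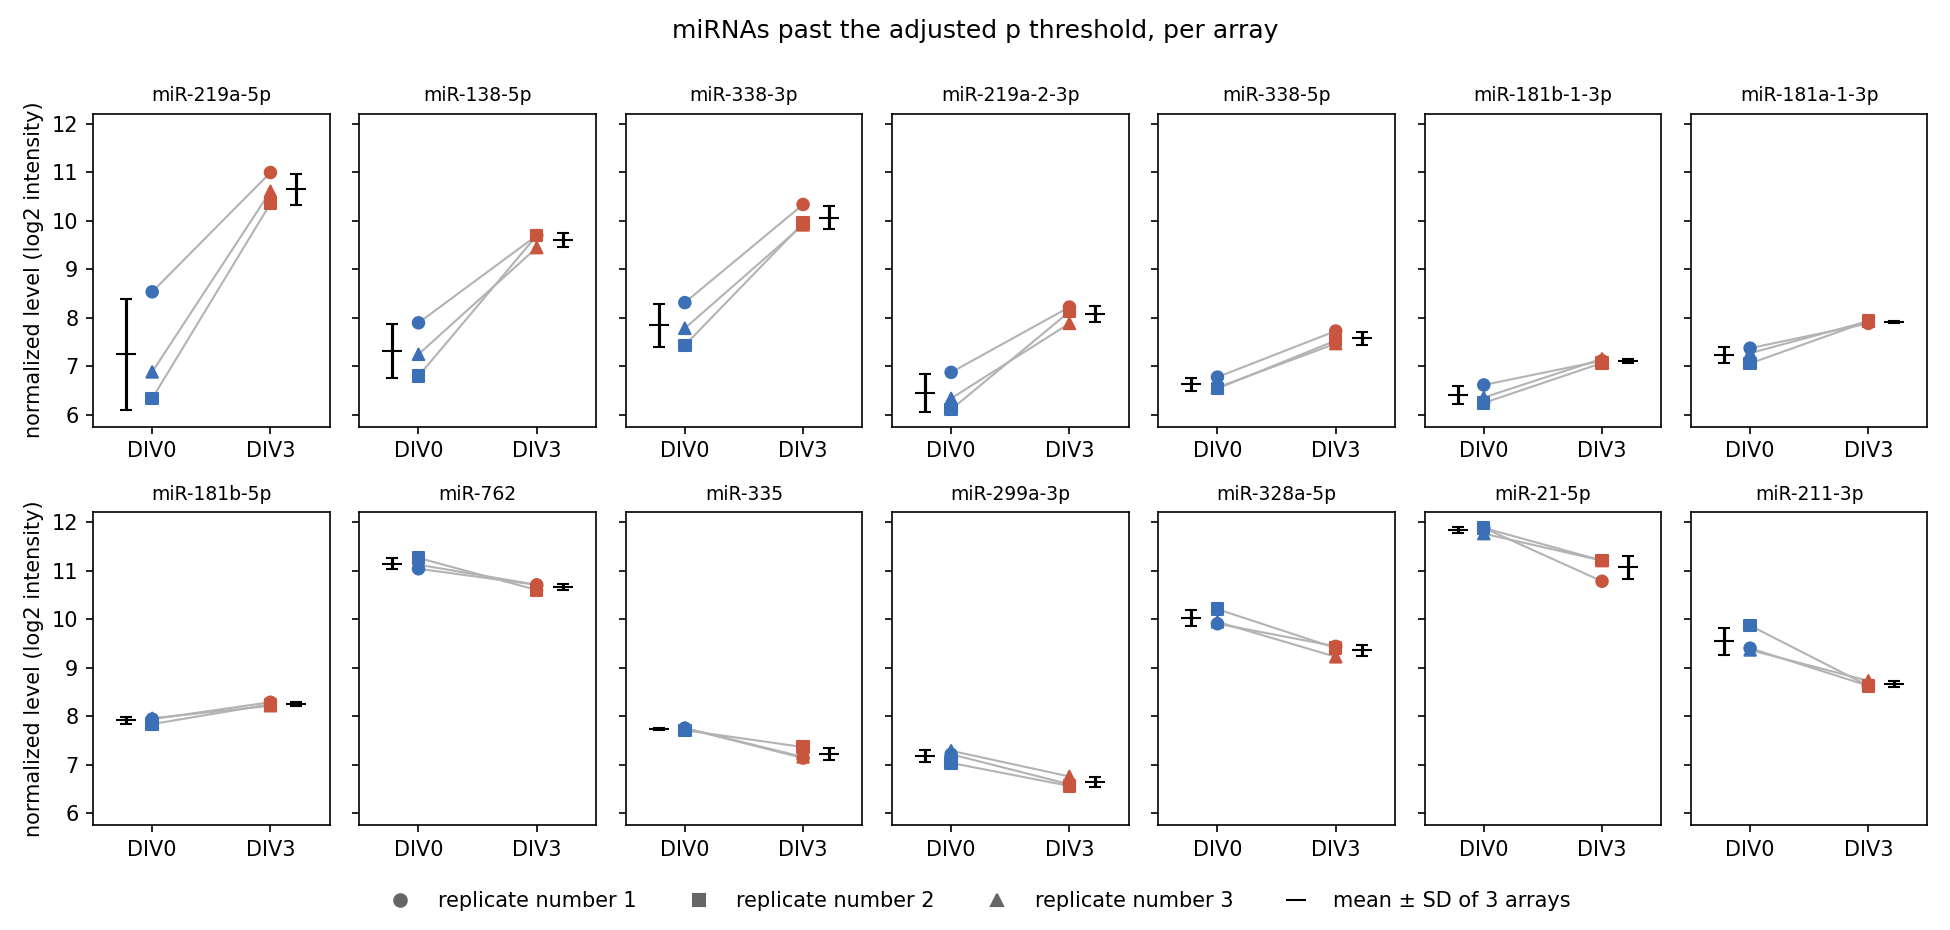
Normalized level (log2 intensity, vertical axis) of the 14 miRNAs past the threshold on each of the 6 arrays. Symbols mark the replicate number, grey lines join arrays of equal number, and black bars give the mean ± SD of 3 arrays; miR-219a-5p differs by 3.40 on this scale and miR-181b-5p by 0.34.

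The number of miRNAs past the threshold depended on single arrays and on the processing. With normexp against the local background, the correction first planned, 1 miRNA passed in place of 14, miR-219a-5p, with a log2 fold change of 2.68. Those of miR-138-5p, miR-338-3p and miR-338-5p were then 0.91, 0.51 and 0.00093 (adjusted p = 0.34, 0.77 and 0.998), and that of miR-219a-2-3p was -0.021. With limma on 5 arrays, 0 passed without the DIV3 array of replicate 1, 2 or 3 or without the DIV0 array of replicate 3, while 72 to 79 had an unadjusted p under 0.05 and the lowest adjusted p was 0.066 to 0.12. In these 4 fits all 14 kept their direction, which the separation of the groups all but fixes. The log2 fold changes were 3.20 to 3.49 for miR-219a-5p, 2.23 to 2.40 for miR-138-5p and 2.06 to 2.31 for miR-338-3p. Without the DIV0 array of replicate 1 there were 13, and without that of replicate 2 there were 7. With the replicate number as a block 26 passed, 12 higher and 14 lower, 13 of them shared with the fit without it, and miR-181b-5p then had an adjusted p of 0.0504. Without both arrays numbered 1, 2 or 3 this count was 1, 32 or 11, so the calls with the block given below also depend on single pairs. The falls were the less secure part: under median scaling of each array 6 miRNAs passed, all 6 higher and 0 lower, and under cyclic loess 8 were higher and 2 lower. Scaling arrays by 1 factor each here means, unless stated, that the offset was added before the scaling. There, miR-328a-5p and miR-762 stood at 0.07 and 0.20 relative to the median of all miRNAs. In the deposited values, scaled by 1 factor without added units, they stood at -0.53 and -0.43. With 16 units added only after scaling to a median of 25, 8 miRNAs passed as higher and 5 as lower. Of these 5, 4 were among the 6 falls, and all 14 kept their direction. From the deposited values 0 passed, with 55 at an unadjusted p under 0.05, although all 14 kept their direction. The log2 fold changes of miR-219a-5p, miR-138-5p and miR-338-3p were then 4.29 ± 0.92, 3.02 ± 0.46 and 2.80 ± 0.40 (SE), and those of miR-219a-2-3p and miR-338-5p were 2.93 and 1.75. Slides 1 and 2 each held 1 array of either condition, and all 14 had the same sign on both. This follows from the separation of the groups and is no further check on the slide. On slide 1 the log2 difference of miR-219a-5p was 2.46 and on slide 2 it was 4.02, those of miR-138-5p were 1.80 and 2.90, and those of miR-21-5p were -1.10 and -0.67. With the slide as a fixed block 0 passed by limma (87 at an unadjusted p under 0.05), with log2 fold changes of 3.24, 2.35 and 2.27 for miR-219a-5p, miR-138-5p and miR-338-3p, and with it as a random block 29 did. In every case the DIV0 array lay at the first position of its slide and the DIV3 array at the second, so position and condition cannot be told apart.

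The list of 13 miRNAs described as raised in or promoting differentiating oligodendrocytes was fixed before the data were examined. Of these, 5 rose and 1 fell over all miRNAs tested, and 6 rose and 2 fell when adjusted over the list alone, or 6 and 3 with the replicate block. The 5 that rose were miR-219a-5p, miR-219a-2-3p, miR-138-5p, miR-338-3p and miR-338-5p, and the member that fell was miR-335. The remaining 7 did not pass: miR-23a-3p (-0.54 ± 0.15), miR-204-5p (-0.73 ± 0.38), miR-146a-5p (-0.31 ± 0.68), miR-219a-1-3p (-0.13 ± 0.06), miR-192-5p (0.21 ± 0.07), miR-184 (0.11 ± 0.07) and miR-32-5p (0.05 ± 0.06). With the replicate block miR-204-5p and miR-23a-3p passed as lower (adjusted p = 0.014 and 0.026). The list as a whole stood higher in DIV3 than the other miRNAs by its mean test statistic (camera adjusted p = 0.019). Its mean log2 fold change was 0.67 and its median 0.11, and 8 of the 13 members lay above the median of all miRNAs. Its adjusted p was 0.43 with an estimated correlation, 0.051 with the replicate block and 0.39 with the local background. In the deposited values its mean lay 1.02 above the median of all miRNAs. By fry, which asks whether the members move one way on balance, it was the only list of 16 that passed (adjusted p = 0.035).

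Of the 11 miRNAs described as high in precursors or as holding differentiation back, 0 rose and 0 fell over all miRNAs tested (limma, 2 at an unadjusted p under 0.05), and 1, miR-27a-3p, fell when adjusted over the list alone, or 3 with the replicate block. The 3 with the lowest p were miR-27a-3p (-0.34 ± 0.06, adjusted p = 0.061), miR-222-3p (-0.45 ± 0.17, adjusted p = 0.30) and miR-221-3p (-0.46 ± 0.23, adjusted p = 0.46). With the replicate block miR-222-3p passed as lower (adjusted p = 0.035). The log2 fold changes of miR-7a-5p, miR-214-3p, miR-212-3p, miR-145-5p, miR-125a-3p and miR-199a-5p lay between -0.09 and 0.02, with standard errors of 0.08 to 0.31. Both arms of miR-9a held the same rank on all 6 arrays, so quantile normalization set their change to 0.00 and measured none. In the deposited values miR-9a-5p had means of 10227 ± 2406 in DIV0 and 13973 ± 882 in DIV3, and miR-9a-3p 3312 ± 530 and 4093 ± 99.0. The set test did not pass for this list (camera adjusted p = 0.11). Its mean lay 0.13 below the median of all miRNAs, a direction that turned to 0.32 above it, with 10 of 11 members above, where arrays were scaled by 1 factor each. In the deposited values, scaled by 1 factor without the added units, it did not turn and stood at -0.085 relative to that median.

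Among the miRNA families, the miR-181 family ranked higher in DIV3 (camera adjusted p = 0.0055, and 0.43 as the adjusted p with an estimated correlation, 4 members, mean log2 fold change 0.33), with 1 member that rose and 0 that fell, and 2 that rose when adjusted over the list alone, or 3 with the replicate block. Next to miR-181b-5p it held miR-181a-5p (0.61 ± 0.12, adjusted p = 0.066, and 0.020 with the replicate block), miR-181d-5p (0.19 ± 0.11) and miR-181c-5p (0.18 ± 0.11). The miR-17-92 clusters, best known from proliferating cells, also ranked higher (adjusted p = 0.019, and 0.43 as the adjusted p with an estimated correlation, 11 members, mean 0.18). None of these members passed over all miRNAs tested, 0 of 11 by limma with 7 at an unadjusted p under 0.05, and with the replicate block 1 rose, miR-19a-3p (0.43 ± 0.13 without the block, adjusted p = 0.22, and 0.032 with it), a member named after its values were seen. When adjusted over the list alone 5 rose and 1 fell, or 6 and 1 with the replicate block. Examples are miR-17-5p (0.42 ± 0.08), miR-19b-3p (0.45 ± 0.11) and miR-20b-5p (0.39 ± 0.09) against miR-25-3p (-0.44 ± 0.12). The miR-30 family ranked higher as well (adjusted p = 0.021, and 0.43 as the adjusted p with an estimated correlation, 5 members, mean 0.16), with 0 members past the threshold over all miRNAs and 1, miR-30e-5p (0.32 ± 0.08), when adjusted over the list alone. Its other members named here were miR-30a-5p (0.18 ± 0.06), miR-30c-5p (0.12 ± 0.11) and miR-30d-5p (0.09 ± 0.06). The miR-23-27-24 clusters ranked lower (adjusted p = 0.019, and 0.43 as the adjusted p with an estimated correlation, 5 members, mean -0.31), with 0 members past the threshold over all miRNAs and 2 lower, miR-27a-3p and miR-23a-3p, when adjusted over the list alone, or 4 with the replicate block. Its miR-24-3p stood at -0.44 ± 0.22, with an adjusted p of 0.032 under the replicate block, where miR-23a-3p also passed as lower, and miR-23b-3p at -0.23 ± 0.14. This direction turned where arrays were scaled by 1 factor each, with a cluster mean 0.35 above the median of all miRNAs, and stayed lower in the deposited values at -0.24 against that median. In the pairs numbered 1, 2 and 3 the mean log2 difference was 0.00093, 0.31 and 0.22 for the miR-17-92 clusters and 0.031, 0.25 and 0.21 for the miR-30 family. It was 0.32, 0.44 and 0.22 for the miR-181 family and -0.35, -0.30 and -0.28 for the miR-23-27-24 clusters. Without the DIV0 array of replicate 2 the adjusted p was 0.057 for the miR-17-92 and the miR-23-27-24 clusters and 0.077 for the miR-30 family. Without the DIV3 array of replicate 3 it was 0.063 for the miR-17-92 clusters and 0.068 for the miR-30 family, and without the DIV3 array of replicate 1 it was 0.061 for the miR-23-27-24 clusters. With the local background the adjusted p was 0.84 for the miR-181 family and the miR-17-92 clusters, 0.89 for the miR-30 family and 0.0050 for the miR-23-27-24 clusters. The size of these changes depended on the processing. The means of the miR-181 family, the miR-17-92 clusters and the miR-30 family lay 0.33, 0.18 and 0.17 above the median of all miRNAs. Where arrays were scaled by 1 factor each, after the offset was added, they lay 0.86, 0.72 and 0.81 above it. In the deposited values, scaled by 1 factor without added units, they lay 0.57, 0.25 and 0.27 above it. Scaling by 1 factor thus did not by itself give the largest means.

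The other 4 families did not pass the set test. The let-7 family, known for its rise as cells mature, had an adjusted p of 0.086, with let-7f-5p at 0.19 ± 0.05, miR-98-5p at 0.14 ± 0.12, let-7c-5p at 0.12 ± 0.11 and let-7b-5p at 0.11 ± 0.11. It passed as higher under median scaling (adjusted p = 4.7e-05) and without the DIV3 array of replicate 3 (0.016), and as lower with the local background (0.013). Its mean lay 0.092 above the median of all miRNAs with 9 of 9 members above it, 0.77 above it where arrays were scaled by 1 factor each, 0.17 in the deposited values, and 0.0049 under cyclic loess, with 4 of 9 members above. The miR-29 family had an adjusted p of 0.062, with miR-29a-3p at -0.57 ± 0.19, miR-29c-3p at -0.24 ± 0.10 and miR-29b-3p at -0.22 ± 0.19. It passed without the DIV0 array of replicate 2 (0.031) or of replicate 3 (0.032). Where arrays were scaled by 1 factor each its direction turned, with a mean 0.21 above the median of all miRNAs and 3 of 3 members above it. In the deposited values it did not turn, at -0.27 with 0 of 3 members above. The miR-15/16 family had an adjusted p of 0.87, and of 0.0070 under median scaling. Its members included miR-15b-5p (-0.20 ± 0.06), miR-497-5p (0.13 ± 0.05), miR-322-5p (0.46 ± 0.25) and miR-16-5p (-0.02 ± 0.05), and its mean of 0.07 and median of -0.01 differ in sign. Its mean was 0.61 above the median of all miRNAs where arrays were scaled by 1 factor each, and that of the family of miR-34 and miR-449 was 0.35 above it. In the deposited values they were 0.20 and 0.14 above it. The family of miR-34 and miR-449 had an adjusted p of 0.90, with miR-34a-5p at 0.13 ± 0.19, miR-34b-5p at -0.08 ± 0.08, miR-34c-5p at -0.07 ± 0.08 and miR-449a-5p at 0.40 ± 0.53. Its mean of 0.09 and the direction of the test, lower in DIV3, differ in sign. In these 4 families 0 members passed over all miRNAs or when adjusted over the list alone (limma, 3 at an unadjusted p under 0.05), and with the replicate block 1 member of the miR-29 family fell when adjusted over the list alone.

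Lists of miRNAs known from other cell types were measured in the same samples. Of 35 tested miRNAs listed from the imprinted Dlk1-Dio3 cluster, which is rich in neurons, 0 passed alone, and the list ranked lower in DIV3 by a mean of -0.06 (camera adjusted p = 0.040). The list holds miR-299a-5p but not its opposite arm miR-299a-3p, which passed as lower. In the pairs numbered 1, 2 and 3 the list mean was 0.025, -0.12 and -0.092. The adjusted p of this list was 0.43 with an estimated correlation, 0.051 with the replicate block, 0.84 with the local background, and 0.057 to 0.26 without the DIV0 array of replicate 2 or 3 or the DIV3 array of replicate 2 or 3. Examples are miR-665 (-0.29 ± 0.08), miR-434-3p (-0.18 ± 0.06), miR-409a-3p (-0.20 ± 0.09) and miR-370-3p (-0.15 ± 0.08). The neuron-enriched list had an adjusted p of 0.17, and of 0.020 without the DIV0 array of replicate 2, with miR-132-3p at -0.23 ± 0.09, miR-128-3p at -0.41 ± 0.16, miR-218a-5p at -0.23 ± 0.20 and miR-137-3p at -0.12 ± 0.10. The astrocyte-enriched list had an adjusted p of 0.19, and of 0.031 without that same array. Its members included miR-31a-5p (-0.78 ± 0.18), the only one lower when adjusted over the list alone, with an adjusted p over all miRNAs of 0.014 under the replicate block, and miR-26a-5p (0.13 ± 0.14). With that block 2 members were lower when adjusted over the list alone. Where arrays were scaled by 1 factor each, the means of the neuron-enriched and astrocyte-enriched lists turned to 0.18 and 0.24 above the median of all miRNAs, and that of the endothelial, mural and fibroblast list from -0.014 to 0.080. In the deposited values these lists stood at -0.093, -0.22 and 0.094. The microglia and blood-cell list had an adjusted p of 0.33. Its members miR-150-5p (-0.22 ± 0.09), miR-155-5p (-0.46 ± 0.34), miR-223-3p (-0.45 ± 0.37) and miR-146a-5p did not pass, and miR-223-3p passed as lower with the replicate block (adjusted p = 0.038), with 2 members lower when adjusted over the list alone. The endothelial, mural and fibroblast list had an adjusted p of 0.81, with miR-126a-5p at 0.18 ± 0.07, miR-126a-3p at -0.06 ± 0.11, miR-10a-5p at 0.13 ± 0.10 and miR-214-3p at -0.08 ± 0.15. The muscle and liver list, taken as miRNAs expected to be low here, had an adjusted p of 0.16, with miR-1-3p at -0.17 ± 0.08, miR-206-3p at -0.21 ± 0.15, miR-122-5p at -0.08 ± 0.06 and miR-133b-3p at -0.07 ± 0.09. Of its 6 members 5 passed the detection criterion on at least 3 arrays.

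**Figure D2:**
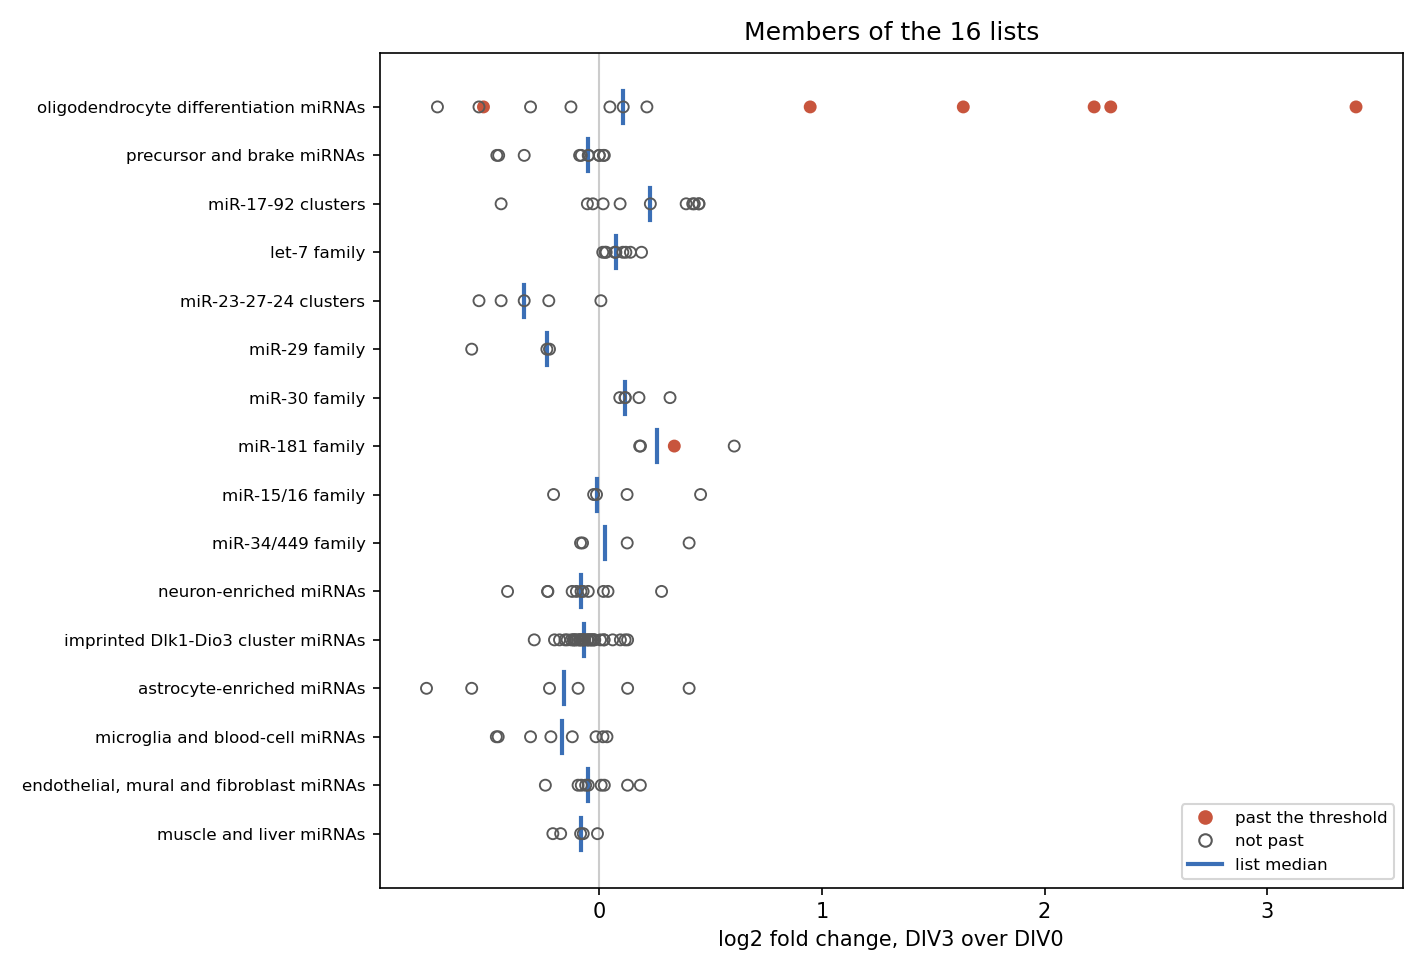
Log2 fold change of DIV3 over DIV0 (horizontal axis) for each tested member of the 16 lists (rows). Filled circles mark the miRNAs past the threshold, open circles the rest and blue bars the list medians; the 5 filled circles of the oligodendrocyte differentiation list between 0.95 and 3.40 lie to the right of the members of every other list.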

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

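Among the control spots, which enter no comparison above, 14 of the 22 singly spotted S-Probes lay above the blank threshold on all 6 arrays. Their targets are not named in the files used here. The brightest of them, S-Probe1014, never read below 4723 units on the scale of the deposited values and averaged 5447 ± 399 in DIV0 and 4832 ± 107 in DIV3 (SD, n = 3). Of the 22 probes 3 reached the smallest exact permutation p that 3 against 3 samples allow, 0.1, and this test could not reach 0.05.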

How the results depend on the processing

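Normexp against the local background was the correction first planned. It was set aside after the columns were seen and before any comparison was run, and gave 1 miRNA and 2 lists past the threshold, 1 of them among the 6 that passed otherwise. The No Probe thresholds, the scaling with 16 units added, the fits without a replicate pair and the test of detected miRNAs within pairs were chosen after seeing the data. With the main settings 14 miRNAs passed, 8 higher and 6 lower. All 14 kept their direction under 24 of the 27 alternatives, and the 3 exceptions are given below. For many alternatives this was fixed in advance: the filters, the trended prior and the replicate block do not alter the fold change. With separated groups, leaving out arrays can hardly turn it. The settings that could turn it were mainly the other background corrections and scalings, which hold the 3 exceptions. The count was 14, the same miRNAs, without a filter, with detection asked on all 6 arrays and with the No Probe filter. It was 14 (9 and 5) with a trended prior, where 12 were shared and miR-181b-5p and miR-335 had adjusted p-values of 0.25 and 0.063, 19 without background correction and 13 (8 and 5) after scaling to a median of 25 with 16 units added, where 11 were shared.

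By limma 0 passed (0 higher, 0 lower) after blank subtraction with a floor of 1, without normalization, from the deposited values and with the slide as a fixed block, where 87, 27, 55 and 87 had an unadjusted p under 0.05. The log2 fold change of miR-219a-5p was then 4.25, 4.03, 4.29 and 3.24, that of miR-138-5p 2.88, 3.04, 3.02 and 2.35 and that of miR-338-3p 2.59, 3.09, 2.80 and 2.27. The fixed slide block leaves 1 residual degree of freedom. An offset of 16 gave 6 (6 and 0), median scaling 6 (6 and 0), 75th percentile scaling 3 (3 and 0) over the miRNAs detected on all arrays and 4 (4 and 0) over all, and cyclic loess 10 (8 and 2). The replicate block gave 26 (12 and 14), and 1 (1 and 0), 32 (13 and 19) or 11 (6 and 5) without the arrays numbered 1, 2 or 3. The slide as a random block gave 29 (17 and 12), and local background 1 (1 and 0). Leaving out 1 array gave 0 to 13, with 0 to 10 higher and 0 to 3 lower. Except for the slide block, the cause was not tested.

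The difference in detected miRNAs ran from -1.83 without DIV3 replicate 1 to 47.3. Of the 6 lists that passed, 0 did with an estimated correlation, 1 by fry, 4 with the replicate block, 5 under median scaling and 2 to 6 with an array left out, with 2 without DIV0 replicate 2 and 3 without DIV3 replicate 3. The let-7 family ranked lower with the local background (adjusted p = 0.013, in a range from 4.7e-05, as higher under median scaling, to 0.43). The miR-23-27-24 clusters turned upward under median scaling (adjusted p = 0.23, against a range that includes 0.0031 with the replicate block and 0.43 with an estimated correlation). With 75th percentile scaling over the detected or all miRNAs the median fold change of all miRNAs shifted by -0.41 or -0.25, and without normalization by 0.26.

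Of the called miRNAs, some turned. With local background the log2 fold change was -0.021 for miR-219a-2-3p, -0.14 for miR-181b-5p, 0.094 for miR-335 and 0.056 for miR-762. Without a turn it went from 2.30 to 0.91 for miR-138-5p, from 2.22 to 0.51 for miR-338-3p, from 0.95 to 0.00093 for miR-338-5p, from 0.71 to 0.20 for miR-181b-1-3p, from 0.68 to 0.30 for miR-181a-1-3p, from -0.54 to -0.053 for miR-299a-3p and from -0.78 to -1.79 for miR-21-5p. Without normalization it was 0.15 for miR-21-5p, 0.33 for miR-328a-5p, 0.14 for miR-335 and 0.46 for miR-762, and relative to the shift of all miRNAs -0.11, 0.07, -0.12 and 0.20. Without a turn it then went from -0.88 to -0.050 for miR-211-3p and from -0.54 to -0.069 for miR-299a-3p. Relative to that shift these were -0.31 and -0.33. Under median scaling miR-762 stood at 0.12. Changes of sign of named miRNAs past the threshold under neither setting, 160 cases, were not counted as reversals. Of the 27 alternatives miR-219a-5p, miR-138-5p and miR-338-3p passed in 17, miR-219a-2-3p in 16, miR-338-5p in 15, and miR-181b-5p in 6. The replicate block changed no other call of a named miRNA over all miRNAs, or of a list by its set test, besides those given in the report. The signal over background was lowest on the DIV0 array of replicate 3, whose median miRNA spot lay 5.87 units above the blanks, and 0 miRNAs passed by limma without this array too (75 at an unadjusted p under 0.05).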

Other observations

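Tests on the spots adjacent to miR-138-5p and miR-219a-5p, the bound on rises of 2-fold or more, and those on subsets of the neighbouring genes, were chosen after the results were seen. With the replicate number as a block, 6 miRNAs outside the rule for named miRNAs passed the threshold, and they are named here after their values were seen. The log2 fold changes were 0.34 for miR-22-5p (adjusted p = 0.038), 0.36 for miR-33-5p (0.032), 0.43 for miR-19a-3p of the miR-17-92 clusters (0.032) and 0.45 for miR-325-3p (0.031), and -0.46 for miR-3593-3p (0.045) and -0.33 for miR-203a-3p (0.043). Each went the same way in 3 of 3 pairs. As the fit with the block picks differences that agree between pairs, this is no separate support.

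A hypothesis was that the 2 arms of a precursor change together because they share its level. Across 271 pairs of arms the log2 fold changes correlated with Pearson r = 0.357 and Spearman rho = 0.21 (one-sided permutation p = 0.00033 and 0.00026, adjusted p = 0.00033 over 2 relations). This is a correlation across miRNAs, which are not independent replicates. Without the 2 pairs farthest out r was 0.257, and over the 259 pairs with neither arm past the threshold it was 0.208 (permutation p = 0.00063). In direction 56.8% of pairs matched. Some arms enter more than 1 pair, which the shuffles treat as separate, and the 2 pairs farthest out both hold miR-219a-5p. The partner arms of miR-138-5p stood at 0.21 and -0.26 against its own 2.30. The data leave room for a shared but loose precursor effect.

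A second hypothesis was that miRNA genes within 10 kb of each other change together because they share a primary transcript. Over 1554 neighbouring pairs from 380 miRNAs the mean absolute difference of log2 fold changes was 0.139, against 0.214 after shuffling (one-sided permutation p = 1e-05, the smallest that the shuffles can give, adjusted p = 2e-05). Shuffled only among miRNAs of similar level the mean was 0.187 (permutation p = 5.0e-05). Leaving out pairs with the same miR number and the chromosome with most pairs left 493 pairs at 0.187 against 0.214 (permutation p = 0.028). Part of the likeness may come from those large clusters and from related sequences. The shuffle among miRNAs of similar level kept those pairs, while the 493 pairs were shuffled over all levels. Related miRNAs with different numbers also stayed in. Shared transcription therefore cannot be told apart from level and related sequences here.

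The 14 miRNAs past the threshold could in principle owe their change to light from neighbouring spots or to one axis of variation among the arrays. On the first, their log2 fold changes correlated at -0.015 with those of the brightest adjacent spot, where spilling light predicted over 0.5. A correlation over all 14 could stay low even if spilling light made single calls, so it cannot exclude that. The first component of the variation within groups held 52.6% of it. Against the second, for the 4 rises of 2-fold or more, this component shifted too little to give any miRNA a log2 fold change above 0.93. These 4 stood at 1.64 to 3.40. On any 5 arrays that bound was at most 1.23, and the smallest of the 4 stood at 1.47 or more. For the other 10 the second stays open: taking the component out left 93.0% of the mean change of all rises and 95.9% of that of the falls, but the threshold picks miRNAs with a small spread beside their change, and 13 of the 14 changed in the direction of its shift. The position on the slide and the time in culture cannot be told apart from the condition. Whether replicates are separate cultures is open, as is differentiation itself, the difference the design names.

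Spilling light was examined separately for miR-181b-5p, whose spot adjoins that of miR-138-5p, and miR-181b-1-3p, whose spot adjoins that of miR-219a-5p. The first gained 12.8% of the change of its bright neighbour and the second 3.70%. Of 250 spots without a probe next to a spot of over 500 units, the median read 0.0472% of the neighbour, the 95th percentile 0.992% and the highest 4.74%. The gain of miR-181b-5p exceeds all of these, which argues against spilling light as its only source on this scale. Both gains were taken from intensities scaled by each array's median, not from the quantile-normalized levels behind the calls. Whether spilling light made part of the gain of miR-181b-5p, or carried its call, stays open. For miR-181b-1-3p the gain lies within the extreme of that range, so this explanation stays open.

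The count of 14 was set against the other splits of the 6 arrays into 3 and 3. Of the 10 splits 1, the real one, gave as many, and the highest count of any other was 0. With the replicate block, 1 of the 4 splits that part all 3 pairs gave as many as 26, and the highest other count was 0. The splits are too few for a share under 0.05.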
